A study of Mus musculus with 24 samples.

How the data were processed

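Bulk RNA sequencing was available for heart, aorta, spleen, lung, liver, kidney, stomach and brain of mice with a human SENCR bacterial artificial chromosome, 3 libraries per tissue. Tissue and replicate number were taken from the sample titles. The design text describes biological triplicates, but nothing in the sources used here says which libraries share an animal. P-values therefore measure the spread between these libraries. Total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V10 RNA-seq kit, per the labels' protocols. Reads were trimmed with fastp, aligned with HISAT2 and counted with HTSeq on GRCh38.p13, a human build, per the submitters' processing notes, which name no versions. The annotation and the strand setting of the counting are not given in the sources used here.

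The authors deposited FPKM, fragments scaled by gene length and by the fragments assigned in each library, with no further scaling between libraries seen in the values. The table held 7493 genes with human symbols in 24 libraries, and 91.4% of the symbols matched a mouse symbol when case was ignored. Because mouse reads were counted on a human build, a mouse gene's value depends on how much of its sequence is shared with the human gene. Levels were therefore compared between tissues within a gene, and levels of different genes or of transgene and mouse genes are not on the same footing. The denominator of each FPKM is the number of reads assigned on the human build, which differed between tissues.

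Low FPKM values of a gene in a library were whole multiples of the value of 1 read. Read numbers were recovered from these steps for 7490 of 7493 genes (99.96%), with a relative tolerance of 1e-06 for a whole number. Recovered totals ran from 177909 to 613544 reads per library, and were 0.993 to 1.05 times the depth implied by the steps. On simulated data the recovery gave the exact number for 99.6% of 6845 genes and 96.3% of all reads, since a gene whose counts share a factor is under-counted. These reads served to state depth and as an alternative, and not in the main tests. A gene without a read could still have up to 3 reads' worth of expression in a library, and such limits cover counting error only, because reads without molecular identifiers are not independent molecules. For SENCR a single read stood behind brain replicate 2 (1.20 FPKM, exact 95% Poisson interval 0.0303 to 6.68).

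Values were analysed as log2(FPKM + 1), so differences understate the change of low genes. Genes with at least 1 FPKM in at least 3 libraries were kept, 4260 in all. limma 3.58.1 in R 4.3.3 was fitted to 8 tissue means with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene was called at an adjusted p under 0.05 and a difference of at least 1. Each tissue was compared with the mean of the other 7, aorta with each other tissue, and tissue-elevated genes were those called higher than each of the 7. On simulated data for aorta against the others (4260 genes, 200 changed), 9.38% of 96 genes changed 2-fold and 92.3% of 104 changed 4-fold were recovered at the adjusted p, and 2 unchanged genes were called. The simulation fixed the overdispersion at 0.1, not estimated from these libraries, and gave the other tissues equal means. Changed genes were not drawn from the lowest ones, so these figures do not give the power over all genes here. SENCR and its neighbours were also tested by an exact two-sided permutation test of 3 libraries against 21, adjusted over 8 tissues, and by permutation over tissues with 100000 resamples. The ratio of SENCR to FLI1 was taken within each library.

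Gene lists for the cell types of these tissues, mitochondrial and ribosomal genes, immediate early genes, proliferation, sex-linked genes and SENCR's neighbours and linked genes were tested with camera in limma. The preset correlation between genes was 0.01, an estimated correlation was run beside it, and p-values were adjusted over 15 lists with at least 3 kept genes and 8 tissues. Mitochondrially encoded genes were matched to the table's own symbols after it had been seen. The genes named are every neighbour or linked gene in the table, the 6 elevated genes per tissue with the largest gap to the next tissue, the 2 largest differences in each direction for aorta against each tissue, and the most abundant members of each list, with further list members given as examples after their values were seen.

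Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, TPM, median-ratio and quantile scaling, leaving out mitochondrially encoded genes, a replicate block, 2 other variance settings, no minimum difference, fits of 6 libraries, an estimated correlation, and each library left out in turn. Chosen after seeing the data were limma voom on recovered reads, thinning to the shallowest library, and leaving out aorta replicates 1 and 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps. Some list results are not reported here. No reference genome was used here, so no coordinates are given.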

Results

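RNA sequencing was carried out on 8 tissues of mice carrying a bacterial artificial chromosome with human SENCR, a long non-coding RNA transcribed antisense to FLI1 and known from vascular smooth muscle and endothelial cells. Heart, aorta, spleen, lung, liver, kidney, stomach and brain were each represented by 3 libraries, 24 in all, and the labels named no animals without the transgene. Values were FPKM of 7493 genes with human symbols, because the reads had been aligned to a human genome. The table therefore held transgene reads together with mouse reads from stretches alike enough in both species to align. Between 177909 reads in liver replicate 3 and 613544 in brain replicate 2 were assigned per library, as recovered from the steps of the FPKM values. Mean assigned reads were 577870 ± 31552 in brain, 467135 ± 106597 in spleen, 438498 ± 14607 in lung and 189350 ± 10266 in liver (SD, n = 3). Replicates correlated at r = 0.939 to 0.965 across genes on the log2(FPKM + 1) scale, and no pair was close enough to be a single library deposited again, with a chi-square per degree of freedom of 2.88 or more.

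The first comparison asked in which tissues the transgenic SENCR transcript was found. SENCR was above 0 in all 24 libraries. Its mean level was highest in kidney (70.7 ± 36.1 FPKM, SD, n = 3), lung (55 ± 19.5), heart (52.7 ± 17.8) and aorta (41.8 ± 17.2). It was lower in spleen (24.8 ± 15.6), liver (13.7 ± 5.60) and stomach (10.7 ± 5.27) and lowest in brain (5.66 ± 4.72). Tissue accounted for 78.0% of the variance in SENCR over the 24 libraries (permutation test over tissues, p = 0.00025).

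Brain SENCR lay 2.49 below the mean of the other tissues on the log2(FPKM + 1) scale (difference -2.49, limma adjusted p = 8.25e-05; exact permutation test, two-sided, adjusted p = 0.0198). It was the only tissue past the threshold in both tests. In limma alone, kidney was higher by 1.59 (adjusted p = 0.00945), lung by 1.28 (adjusted p = 0.0351) and heart by 1.22 (adjusted p = 0.0330), and stomach differed by -1.37 (adjusted p = 0.0278); the permutation adjusted p values of these were 0.257, 0.262, 0.262 and 0.262. The permutation test set 3 libraries against 21 that themselves differed by tissue, whereas limma used the spread within tissues. Aorta (0.82, limma adjusted p = 0.163), liver (-0.94, 0.0910) and spleen (-0.10, 0.866) passed neither test. The difference was 0.53 in aorta without aorta replicate 1, -0.57 in liver without liver replicate 1 and -0.91 in stomach without stomach replicate 2, and in spleen it was 0.21 without spleen replicate 2 and -0.56 without spleen replicate 1. The permutation call in brain ended when brain replicate 1, 2 or 3 was left out, with adjusted p of 0.0632, 0.129 and 0.0949.

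Between pairs of tissues, SENCR differed in 13 of 28 comparisons. Aortic SENCR exceeded that of brain by 2.90 (limma adjusted p = 0.000384), stomach by 1.92 (adjusted p = 0.0194) and liver by 1.54 (adjusted p = 0.0469), with a standard error of 0.59 for each difference. It was not separated from heart (-0.35), kidney (-0.67), lung (-0.40) or spleen (0.81). Brain, the lowest by mean, was not separated from liver (-1.36, limma adjusted p = 0.0654) or stomach (-0.98, 0.203). These values rested on few reads, between 11 in the 3 liver libraries and 102 in the 3 lung libraries. Brain had 13 reads and stomach 12, so the lower FPKM of brain rested on its larger number of assigned reads. SENCR and FLI1 overlap on opposite strands, and the strand setting of the counting is not given in the sources used here, so reads of the pair could not be told apart with certainty.

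FLI1, an ETS-family transcription factor of endothelial and blood cells, followed another order of tissues. Its mean was 696 ± 346 FPKM in spleen and 565 ± 263 in lung (SD, n = 3), 218 ± 97.7 in heart, 192 ± 71.2 in aorta, 125 ± 59.7 in kidney, 79.1 ± 44.6 in liver, 51.9 ± 24.3 in stomach and 38.1 ± 14.1 in brain. Spleen was higher than the mean of the others by 2.48 (limma adjusted p = 7.33e-05; exact permutation adjusted p = 0.0435) and lung by 2.14 (limma adjusted p = 0.000525; permutation adjusted p = 0.0593). Brain (-2.23, limma adjusted p = 0.000122; permutation adjusted p = 0.0593), stomach (-1.78, 0.00295; permutation 0.128) and liver (-1.20, 0.0229; permutation 0.361) were lower in limma. The liver difference was -0.62 without liver replicate 2. Brain was not separated from liver (-0.90, limma adjusted p = 0.196) or stomach (-0.40, 0.620). It had 349 FLI1 reads, against 247 in liver and 232 in stomach, over a larger number of assigned reads. The permutation call in spleen was marginal. It ended under TPM scaling (adjusted p = 0.0553), under median-ratio scaling (0.0929), without mitochondrially encoded genes (0.0553), and when any of 10 libraries was left out: spleen replicate 1 (0.138), 2 (0.0587) or 3 (0.0572), brain replicate 1 (0.0723), 2 (0.0542) or 3 (0.0723), heart replicate 2 (0.0542), liver replicate 1 (0.0542) or 3 (0.0632), or stomach replicate 1 (0.0610). Conversely, brain passed the permutation test without kidney replicate 2 (0.0497), liver replicate 2 (0.0316), stomach replicate 2 (0.0294) or stomach replicate 3 (0.0497), and lung without spleen replicate 1 (0.0452). Brain also passed under quantile normalization (0.0455) and with voom on recovered reads (0.0494). With a replicate block brain and lung both passed (0.0290 for each), although the labels do not say what the replicate numbers share.

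KCNJ1, the potassium channel of the thick ascending limb and collecting duct, was almost restricted to kidney among the sampled tissues. It reached 1497 ± 498 FPKM there (SD, n = 3; 4154 reads in the 3 libraries), against 4 reads in lung, 1 read in aorta and none in the other 5 tissues. The kidney difference was 10.3 on the log2(FPKM + 1) scale (limma adjusted p = 1.06e-16; exact permutation adjusted p = 0.00395, from the smallest p this test can give, 0.000494). ETS1, the other ETS factor of the locus, was highest in spleen (76.0 ± 26.0 FPKM) and lung (26.1 ± 5.54), and its spleen difference of 3.58 passed both tests (limma adjusted p = 1.25e-07; permutation adjusted p = 0.00395). BARX2 was highest in stomach (4.51 ± 6.32 FPKM, up to 11.7 in a library), where limma called it (1.39, adjusted p = 0.0279; exact permutation adjusted p = 0.251), and KCNJ5 and ARHGAP32 stayed under 1 FPKM on average in every tissue. Of 5 genes linked to SENCR in vascular cells, CKAP4 was in the table, at no more than 0.76 FPKM on average in any tissue. Which of these reads came from the transgene and which from the mouse gene was not determined.

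The ratio of SENCR to FLI1 FPKM within a library differed by tissue (permutation test, p = 0.00185). FLI1 reads may come from the mouse gene as well as the transgene, and the strand setting is unknown. The ratio therefore does not measure the relative output of the pair. The ratio was highest in kidney (56.7% ± 9.55, SD, n = 3; exact permutation test against the other tissues, adjusted p = 0.0277) and lowest in spleen (3.43% ± 0.507, adjusted p = 0.00395). Aorta (21.6% ± 3.61), stomach (20.6% ± 6.18), lung (10.1% ± 2.06), brain (13.3% ± 9.33), heart (30.4% ± 20.8) and liver (27.8% ± 28.1) lay between, and none passed the test (adjusted p = 0.756 for each).

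**Figure D1:**
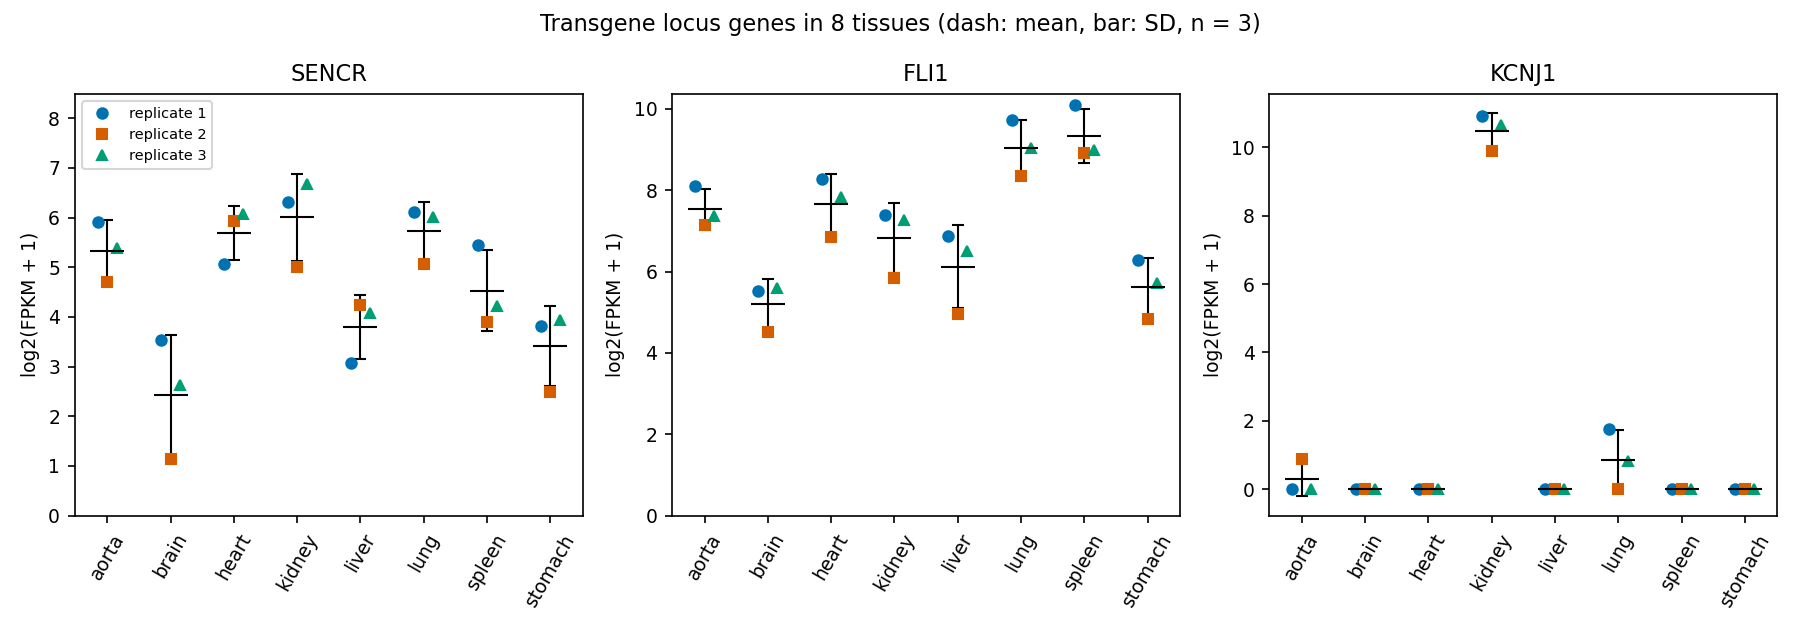
Level of SENCR, FLI1 and KCNJ1 on the log2(FPKM + 1) scale (vertical axes) in each tissue (horizontal axis), with 3 libraries per tissue shown as points, their mean as a dash and the SD as a bar. SENCR lies lowest in brain, FLI1 highest in spleen and lung, KCNJ1 stands apart in kidney, and replicate 2 is the lowest FLI1 point in each of the 8 tissues.

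Each tissue was then set against the mean of the other 7 to describe which genes set it apart, over 4260 genes with at least 1 FPKM in at least 3 libraries. Calls needed a limma adjusted p under 0.05 and a difference of at least 1 on the log2(FPKM + 1) scale. Genes called higher than in every other tissue are named tissue-elevated below, and 1027 genes met this. Gene lists chosen before the data were examined were tested as sets, with the symbols of the mitochondrial list matched afterwards, and counts of their members were the same adjusted over the list alone except where given. The filter asks for 3 libraries, the number per tissue, so a gene silent elsewhere could pass through 1 tissue alone. Such members raise the count of higher genes in that tissue by construction.

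Aorta was marked by matrix and smooth muscle genes. SFRP2, a secreted Wnt modulator, was at 420.1 ± 87.4 FPKM against 15.8 ± 5.19 in lung, the next tissue (SD, n = 3). TWIST1, a mesenchymal transcription factor, was at 110.2 ± 10.7 against 5.51 in lung, smooth muscle actin ACTA2 at 48.3 ± 4.68 against 2.98 in stomach, and the integrin-like matrix protein ITGBL1 at 13.7 ± 1.85 against 0.45 in lung. Of 9 smooth muscle contractile genes, 8 were higher and 1, DES, was lower (camera adjusted p = 2.00e-07; adjusted p = 0.00298 with an estimated correlation; 8 and 1 adjusted over the list alone). Among them SMTN was at 104.4 ± 27.5 FPKM, ACTG2 at 61.4 ± 12.3 and TPM1 at 1050.3 ± 91.5. Not all were highest in aorta, since ACTG2 reached 189.8 FPKM in stomach and TPM1 19876 FPKM in heart. Of 7 fibroblast and matrix genes, COL1A1 (181.6 ± 15.0 FPKM), FBLN5 (231.5 ± 26.0) and FN1 (29.0 ± 12.7) were higher (camera adjusted p = 0.000165; adjusted p = 0.0230 with an estimated correlation).

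All 11 mitochondrially encoded genes were also called higher in aorta, led by COX1 (77.6 ± 94.9 FPKM), ND4 (72.8 ± 67.5) and COX3 (67.7 FPKM). The list's call was lost with an estimated correlation (adjusted p = 0.251). These values came from aorta replicates 1 and 3, with 363 and 216 reads of such genes against 6 in aorta replicate 2. Without those 2 libraries the list's mean difference was -0.0159 (adjusted p = 0.756), and ND4 (adjusted p = 0.274) and COX1 (adjusted p = 0.481) were not called. In the same comparison 9 of 22 cytosolic ribosomal protein genes were higher (adjusted p = 0.249 with an estimated correlation). Their mean difference was 0.86, or 0.36 without aorta replicates 1 and 3 (camera adjusted p = 0.139) and 0.36 with a filter at 5 FPKM (0.178). RPL4 had 7 reads in aorta replicate 1, 1 in replicate 3 and none in replicate 2, and RPL3 had 3, 3 and none. RPL8 went another way, with 3 reads in aorta replicate 1, 1 in replicate 2 and none in replicate 3. Also higher were 5 of 12 immediate early and heat shock genes, among them DUSP1 at 98.5 ± 7.53 FPKM (6 adjusted over the list alone; camera adjusted p = 0.0422; adjusted p = 0.326 with an estimated correlation). That list's call at the preset correlation also ended without aorta replicate 2 (0.0631), aorta replicate 3 (0.107), aorta replicates 1 and 3 together (0.0783), liver replicate 2 (0.0531) or spleen replicate 1 (0.0583). It ended as well with a pseudocount of 0.1 (0.0727), no filter (0.110), a filter at 5 FPKM (0.163), median-ratio scaling (0.0532) and thinning (0.0620). In all, 408 genes were higher and 349 lower in aorta, and 70 were aorta-elevated, or 41 without aorta replicates 1 and 3, 43 under TPM scaling and 39 with a pseudocount of 0.1. Under TPM scaling the split was 399 higher and 607 lower, with mitochondrially encoded genes left out 330 and 485, and with voom on recovered reads 597 were lower.

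Brain had the most elevated genes, 564. SNAP25, which drives synaptic vesicle fusion, was at 4960.4 ± 404 FPKM against 23.0 ± 4.82 in stomach, the next tissue (SD, n = 3). The AMPA receptor subunit GRIA2 was at 1059 ± 136 FPKM, the neuronal kinesin KIF5A at 1429 ± 45.9, the AMPA receptor auxiliary protein CNIH2 at 2176 ± 211 and the potassium channel gene KCNC1 at 261.7 ± 5.45. NEUROD6, a neuronal transcription factor, was at 350.2 ± 49.2 FPKM and listed at 0 in the other 7 tissues. All 17 neuron genes were higher (camera adjusted p = 3.75e-13; adjusted p = 0.00298 with an estimated correlation). MBP, a myelin protein gene, was at 271.1 ± 65.3 FPKM and SOX10, a glial transcription factor, at 8.42 ± 6.40. Of 9 smooth muscle genes 8 were lower (adjusted p = 0.0321 with an estimated correlation). The reference mean includes aorta, where 8 of these genes were higher, which lowers the other tissues by construction. Of 22 ribosomal protein genes 11 were lower (adjusted p = 0.232 with an estimated correlation). In all, 1019 genes were higher and 449 lower, or 791 and 851 under quantile normalization, and voom on recovered reads gave 989 lower.

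Heart was set apart by the sarcomere. ACTC1, cardiac actin, was at 48354 ± 5538 FPKM against 1038 ± 143 in lung (SD, n = 3), and MYH6, the alpha myosin heavy chain, at 5461 ± 597 against 29.7 ± 15.1 in lung. Sarcomeric creatine kinase CKMT2 (245.3 ± 49.2 FPKM), troponin C gene TNNC1 (102.3 ± 14.5) and the non-coding RNA MHRT (170.2 ± 20.1) were listed at 0 in the other 7 tissues, and ACTN2 was at 229.3 ± 29.9. MHRT overlaps the myosin heavy chain genes, so its reads are uncertain. Of 13 cardiomyocyte genes 12 were higher (camera adjusted p = 1.08e-29; adjusted p = 0.000515 with an estimated correlation), MYL7 being the exception. Of 7 nuclear genes of oxidative phosphorylation 5 were higher (adjusted p = 0.0321 with an estimated correlation; 6 adjusted over the list alone), with ATP5F1B at 2134 ± 149 FPKM, NDUFS1 at 113.5 ± 8.65 and COX5A at 100.7 ± 54.0. In all, 273 genes were higher and 743 lower, and 70 were heart-elevated. Median-ratio scaling gave 426 higher and 400 lower and quantile normalization 426 and 358, so that the excess of lower genes depended on the scaling.

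Kidney combined tubule and homeobox genes. KCNJ1 was followed by HOXD10 at 324.4 ± 40.8 FPKM against 3.60 in aorta and HOXD8 at 262.1 ± 25.1 against 12.5 in aorta (SD, n = 3). HOXA10-HOXA9, a readthrough gene that shares exons with HOXA10 and HOXA9 and so is uncertain, was at 27.3 ± 9.15 FPKM and the sodium-potassium-chloride transporter SLC12A1 at 21.9 ± 1.63, both listed at 0 in the other 7 tissues, and the kidney transcription factor PAX8 was at 20.4 ± 4.89 FPKM. Of 4 kidney tubule genes 3 were higher, KCNJ1, SLC12A1 and CALB1 at 9.0 ± 4.45 FPKM (adjusted p = 0.00926 with an estimated correlation). Of 17 neuron genes 10 were lower (adjusted p = 0.0233 with an estimated correlation; 11 adjusted over the list alone), against a mean of tissues that includes brain, where all 17 were higher, so a lower value outside brain follows largely from that reference. In all, 416 genes were higher and 346 lower, or 339 and 399 under median-ratio scaling, and 72 were kidney-elevated, or 47 with a pseudocount of 0.1.

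Liver was marked by HAO1, a peroxisomal glycolate oxidase, at 1938 ± 154 FPKM against 5.62 ± 9.74 in stomach (SD, n = 3). The urea cycle enzyme CPS1 was at 117.4 ± 26.3, fibrinogen alpha FGA at 197.4 ± 24.7, the glutamine transporter SLC38A3 at 153.6 ± 32.9, liver glutaminase GLS2 at 60.5 ± 20.97 and the sterol carrier SCP2 at 522.0 ± 153 FPKM. Of 7 hepatocyte genes 4 were higher, FGA, CPS1, ASS1 (54.8 ± 25.9 FPKM) and CYP2E1 (2.91 ± 0.157), and the call held with an estimated correlation (adjusted p = 0.0321). ALB, the main plasma protein gene of the liver, was at 0.75 ± 1.30 FPKM, and APOA1 and TTR were listed at 0 in liver. In all, 418 genes were higher and 737 lower, or 495 and 573 under quantile normalization, and 82 were liver-elevated.

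Lung was led by NKX2-1, the lung and thyroid transcription factor, at 216.1 ± 9.33 FPKM against 0.70 in brain (SD, n = 3). RAMP2, part of the adrenomedullin receptor, was at 30.8 ± 26.9, TBX4 at 19.6 ± 8.51, FOXF2 at 11.6 ± 2.08 and the non-coding LINC02178 at 16.1 ± 10.7 FPKM. The fast muscle gene MYOZ1 was at 69.6 ± 45.9 against 8.80 ± 9.29 in stomach. All 7 skeletal muscle genes tested were higher, among them MYH2 (22.1 ± 9.87 FPKM) and ACTA1 (22.3 ± 25.3), but the call was lost with an estimated correlation (adjusted p = 0.166). All 4 endothelial genes were higher, TEK at 17.2 ± 4.07, ERG at 6.90 ± 3.05, ENG at 3.45 ± 3.48 and CLDN5 at 2.09 ± 1.36 FPKM (adjusted p = 0.0673 with an estimated correlation). In all, 508 genes were higher and 155 lower, median-ratio scaling gave 367 and 198, quantile normalization 352 and 229, and voom on recovered reads 448 lower. There were 54 lung-elevated genes, or 32 with a pseudocount of 0.1.

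Spleen was set apart by genes such as TLX1, IKZF1 and POU2F2. TLX1, a homeobox gene of the developing spleen, was at 11.6 ± 2.19 FPKM and listed at 0 in the other 7 tissues (SD, n = 3). The lymphoid transcription factor IKZF1 was at 30.2 ± 3.65, POU2F2 at 34.7 ± 16.5, ARHGAP15 at 22.6 ± 9.46, COCH at 9.85 ± 8.51 and the replication gene TOP2A at 49.0 ± 43.0 FPKM. Of 22 ribosomal protein genes 12 were higher, with RPLP0 at 5597 ± 760.0 FPKM, RPL11 at 2397 ± 720.4 and RPS4X at 1790.3 ± 346, and the call was lost with an estimated correlation (adjusted p = 0.249). PAX5, of the B lineage, was at 58.7 FPKM and SPI1, of the myeloid lineage, at 163.1 FPKM; their lists had a single gene that passed the filter and were not tested. Spleen replicate 3 stood apart from replicates 1 and 2, with a chi-square per degree of freedom of 14.3 and 13.04. In all, 488 genes were higher and 576 lower, TPM scaling gave 422 and 767, quantile normalization 554 and 520, and voom on recovered reads 1089 lower. There were 64 spleen-elevated genes, or 36 under TPM scaling and 39 with a pseudocount of 0.1.

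Stomach showed epithelial and smooth muscle genes. GALNT7, a mucin-type glycosyltransferase, was at 103.6 ± 9.46 FPKM against 4.04 ± 1.90 in spleen, and GMDS, an enzyme of GDP-fucose synthesis, at 111.5 ± 17.0 against 6.26 ± 2.27 in kidney (SD, n = 3). BARX1, a stomach mesenchyme factor, was at 22.3 ± 13.4 FPKM and listed at 0 in the other 7 tissues, PITX1 was at 37.2 ± 2.01 and the anion transporter SLC26A9 at 22.3 ± 5.05. Of 3 squamous epithelium genes all were higher, KRT17 (42.8 ± 24.4 FPKM), KRT14 (23.8 ± 16.8) and KRT6A (2.33 ± 1.37), with adjusted p = 0.0493 with an estimated correlation. Of 9 smooth muscle genes 4 were higher, led by ACTG2 at 189.8 ± 23.3 and TPM1 at 1224 ± 169 FPKM (adjusted p = 0.0233 with an estimated correlation). TPM1 was higher still in heart, at 19876 FPKM. In all, 326 genes were higher and 250 lower, 51 were stomach-elevated, TPM scaling gave 309 and 373 and median-ratio scaling 264 and 286.

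**Figure D2:**
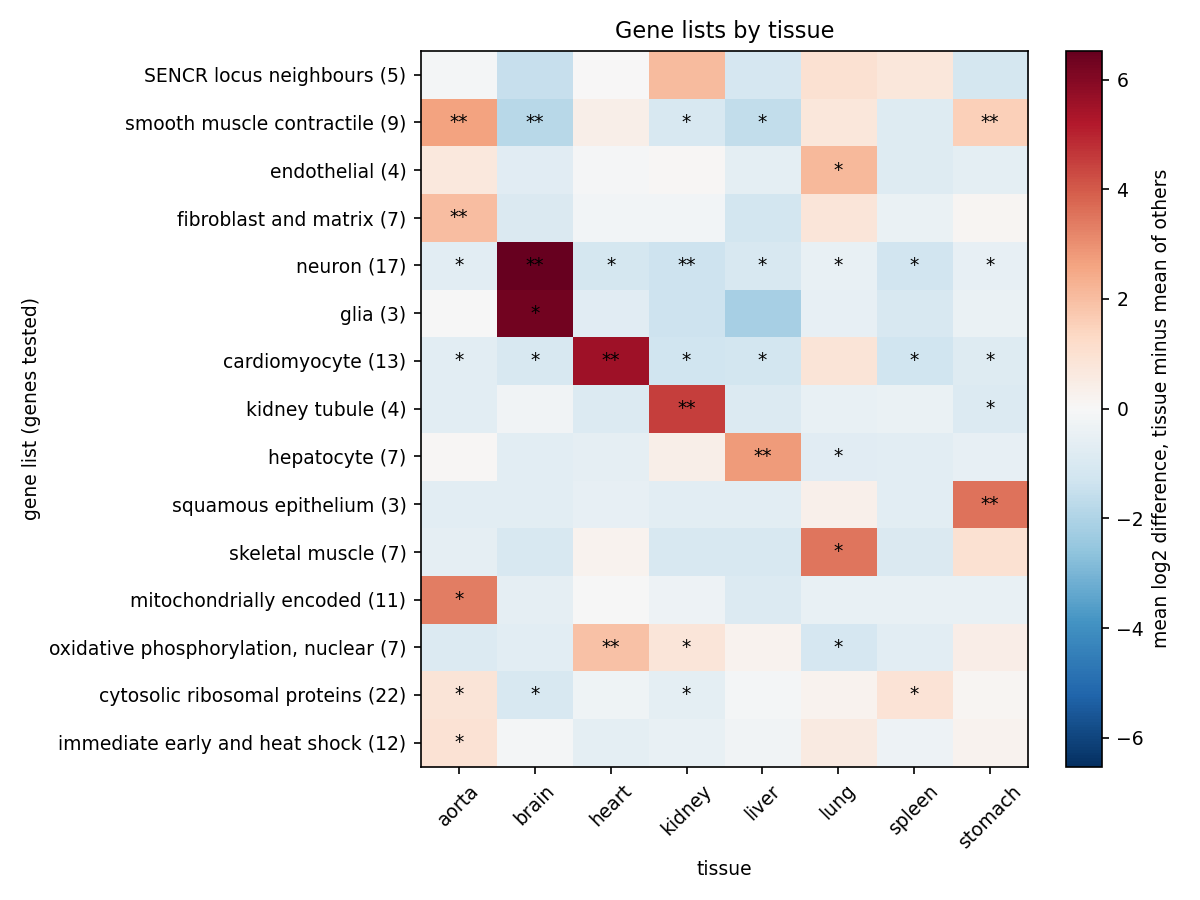
Mean log2 difference of each gene list (vertical axis, with the number of genes tested) in each tissue (horizontal axis) against the mean of the others, in red for higher and blue for lower. One star marks a camera call at the preset correlation and a double star a call that also held with an estimated correlation, such as cardiomyocyte genes in heart (0.000515) and smooth muscle genes in aorta (0.00298).

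Over 15 lists with at least 3 genes past the filter and 8 tissues, 38 of 120 tests were called at the preset correlation and 11 with an estimated correlation. Of 17 neuron genes, 3 were lower in aorta (adjusted p = 0.184 with an estimated correlation), 7 in heart (0.219), 9 in liver with 1 higher (0.219), 5 in lung with 2 higher (0.133), 11 in spleen (0.0673) and 4 in stomach with 1 higher (0.160), and these list calls were lost with an estimated correlation. The reference mean includes brain for these genes and heart for cardiomyocyte genes, which lowers the other tissues by construction. Of 13 cardiomyocyte genes, 3 were lower and 1 higher in aorta (adjusted p = 0.254 with an estimated correlation), and 3 were lower in brain (0.251), 4 in kidney (0.116), 4 in liver (0.251), 4 in spleen (0.171) and 2 in stomach (0.160). Of 9 smooth muscle genes 5 were lower in kidney (0.128) and 7 in liver (0.110). These calls were lost too, and the reference mean for smooth muscle genes includes aorta, where 8 were higher. Nuclear genes of oxidative phosphorylation were lower in lung, 3 of 7 (4 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation). In kidney 2 of 7 were higher (0.268), a call that ended without heart replicate 1 (0.0555), kidney replicate 1 (0.050), kidney replicate 3 (0.0656) or liver replicate 3 (0.0511). It ended as well with a pseudocount of 5 (0.0573), no filter (0.179, mean 0.31 against 0.77), a filter at 5 FPKM (0.0690) and without mitochondrially encoded genes (0.0506). Ribosomal protein genes were lower in kidney, 4 of 22 (0.365), a call that ended without kidney replicate 3 (0.0688). Hepatocyte genes were lower in lung, 3 of 7 (0.133), and 1 of 4 kidney tubule genes was lower in stomach (0.133). The list of SENCR locus neighbours was not called in any tissue. Other lists had fewer than 3 genes past the filter. Lung epithelium was represented by NKX2-1, erythroid cells by TFRC (114.1 FPKM in spleen), adipocytes by DGAT2 (509.3 FPKM in liver) and PPARG (26.3 FPKM in stomach), and proliferation by TOP2A and PLK1 (1.42 FPKM in spleen). ATP4A, PGC and CHIA of gastric epithelium were at 2.59, 2.22 and 1.64 FPKM in stomach and did not pass the filter. The Y-linked UTY was between 0.84 FPKM in stomach and 3.62 in spleen on average and DDX3Y between 0 in brain and kidney and 1.30 in spleen.

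Aorta was finally compared with each tissue separately, since SENCR is known from vessel wall cells. Against brain, 548 genes were higher and 1035 lower; the matrix gene IGFBP7 (1321 ± 148 FPKM in aorta, 3.60 ± 6.23 in brain) and S100A6 (870.5 ± 149 and 12.4 ± 18.7) were highest, and SNAP25 (-10.16) and KIF5A (-9.59) lowest on the log2(FPKM + 1) scale. Against heart, 689 were higher and 277 lower, with NNAT (637.3 ± 381 against 5.17 ± 4.60 FPKM) and HOXC6 (127.7 ± 8.03 against 0.44 ± 0.756) higher and MYH6 (-12.12) and MYH7 (-10.18) lower. Against kidney, 505 were higher and 586 lower, with the mesenchymal filament VIM (263.3 ± 40.1 against 0.93 ± 0.804 FPKM) and FOXP2 (330.2 ± 33.1 against 1.96 ± 1.43) higher and KCNJ1 (-10.19) and the sodium pump subunit ATP1B1 (-6.72) lower. Against liver, 762 were higher and 562 lower, with NNAT and SFRP2 at 637.3 ± 381 and 420.1 ± 87.4 FPKM in aorta and listed at 0 in liver, and HAO1 (-10.28) and the gap junction gene GJB1 (-8.47) lower.

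Lung was the tissue with the fewest genes called against aorta, 198 higher and 362 lower. HOXC6 (6.36) and HOXC8 (50.3 ± 24.5 FPKM in aorta, listed at 0 in lung) were higher in aorta, and NKX2-1 (216.1 ± 9.33 FPKM in lung, listed at 0 in aorta) and the uncoupling protein gene UCP2 (-5.24) were lower. Against spleen, 578 were higher and 509 lower, with SFRP2 (8.29) and NNAT (7.64) higher and the B cell factor BCL11A (-7.18) and the cell cycle gene CKS2 (-6.55) lower. Against stomach, 459 were higher and 448 lower, with FBLN5 (5.69) and HOXC10 (40.3 ± 10.4 FPKM in aorta, listed at 0 in stomach) higher and CKMT1B (1321 ± 167 FPKM in stomach) and FOXQ1 (371.3 ± 86.0), both listed at 0 in aorta, lower. CKMT1B has a near-identical copy, so its value is uncertain. All genes named for these comparisons had limma adjusted p of 4.31e-06 or less.

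HOX genes, which record position along the body axis, were looked at as a family after their values had been seen. Of 25 that passed the filter, 22 were higher in kidney and 19 in aorta, with none lower in either. None was higher in heart, liver or spleen, where 20, 20 and 19 were lower. In brain 15 were lower and 1 higher, in lung 8 lower and 6 higher, and in stomach 7 lower and 4 higher. The reference mean for these tissues includes kidney and aorta, which lowers them by construction. Of the 9 genes of groups 9 to 11, all were higher in kidney (median difference 5.48) and 6 in aorta (2.00). HOXC10 was at 149.5 ± 14.7 FPKM in kidney and 40.3 ± 10.4 in aorta (SD, n = 3), and HOXA5 was highest in lung (718.5 ± 40.6) and aorta (392.1 ± 39.8). Between aorta and kidney, HOXD10 (-6.57, limma adjusted p = 5.21e-07), HOXD8 (-4.56, 9.00e-06) and HOXD9 (-3.19, 0.000265) were lower in aorta and HOXA2 was higher (3.38, 0.000665). In kidney and aorta no HOX gene was called lower under TPM scaling, median-ratio scaling or quantile normalization, with 23, 22 and 22 higher in kidney and 21, 20 and 20 in aorta. Neighbouring HOX genes overlap and resemble each other, so reads of single genes are uncertain.

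**Figure D3:**
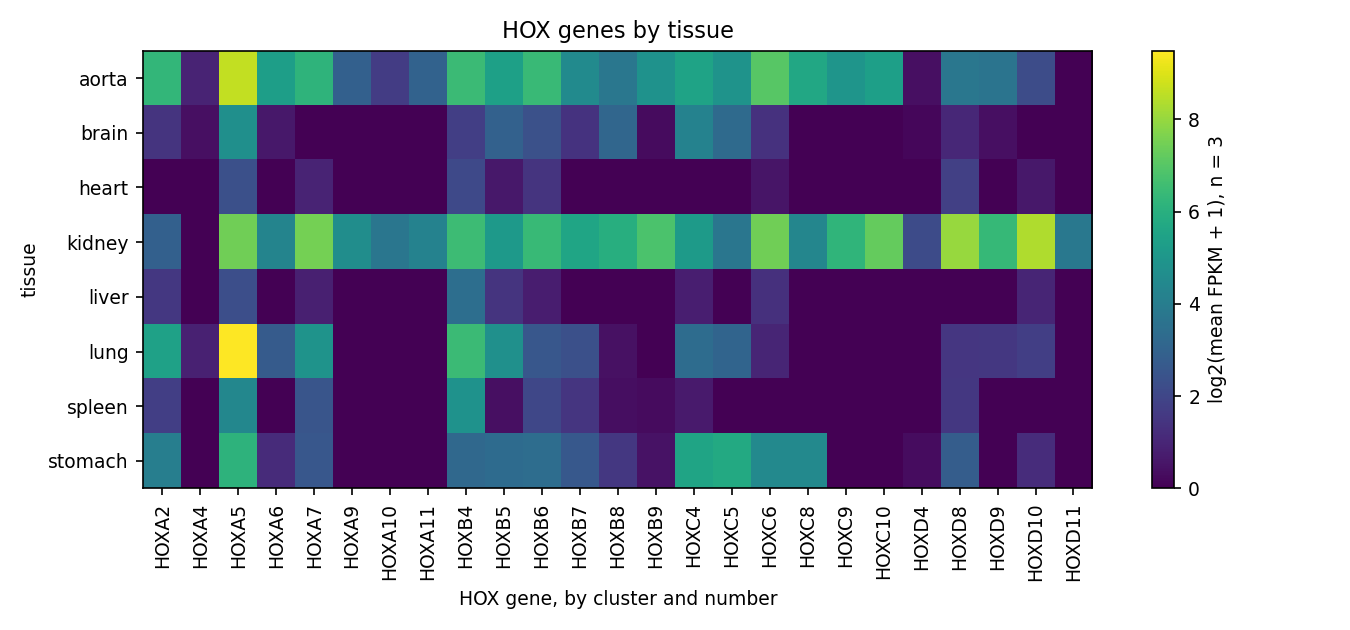
Mean level of 25 HOX genes (horizontal axis) in 8 tissues (vertical axis), drawn as log2(mean FPKM + 1) over 3 libraries. Kidney and aorta hold most of the high values, and genes of groups 9 to 11 lie near 0 in the other tissues.

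The balance of higher and lower genes in these comparisons moved with the scaling. Under TPM scaling the aorta gave 389 higher and 1297 lower against brain, 537 and 345 against heart, 428 and 819 against kidney and 152 and 471 against lung. Median-ratio scaling gave 508 and 413 against heart, 605 and 448 against kidney, 255 and 243 against lung, 659 and 374 against spleen and 555 and 306 against stomach. Quantile normalization gave 793 and 788 against brain, 441 and 452 against heart and 253 and 240 against lung, and with mitochondrially encoded genes left out the aorta gave 373 and 1312 against brain, 497 and 331 against heart and 394 and 802 against kidney. With aorta replicate 2 as the sole aorta library, aorta against lung gave 233 lower and aorta against stomach 287 higher, the lone library being assumed to vary like the other tissues. The median gene stood at -0.44 in heart as deposited, and median-ratio scaling moved it by 0.22 and quantile normalization by 0.26. The median moved by -0.33 in brain and -0.25 in lung under quantile normalization and by 0.30 in brain under TPM scaling, so differences of that size depend on the scaling.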

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

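The voom, thinning and aorta-library alternatives were chosen after the results were seen. With 1 library left out, 1824 of 1824 values of named genes and 903 of 912 list results kept their direction and side of the threshold, and 936 of 936 counts stayed within 1.5 times. Under the other settings 1092 of 1094, 520 of 573 and 510 of 578 did so. Direction and side held for SENCR in 187 of 192 and 112 of 113 values, for FLI1 176 of 192 and 106 of 113, and for KCNJ1 24 of 24 and 14 of 14. Where a value changed, the cause was not tested unless named. Over single libraries left out, SENCR ran from -3.05 to -1.85 in brain and from -0.56 to 0.21 in spleen, and FLI1 from -2.43 to -1.89 in brain, -0.66 to 0.11 in kidney, 1.79 to 2.48 in lung and 2.10 to 2.69 in spleen. A pseudocount of 0.1 left 39 elevated genes in aorta, 47 in kidney, 32 in lung and 39 in spleen. A pseudocount of 5, which shrinks differences of low genes by construction, gave 221 higher and 133 lower in aorta, 635 and 275 in brain, 153 and 303 in heart, 251 and 126 in kidney, 272 and 313 in liver, 244 and 55 in lung, 249 and 263 in spleen, 163 and 75 in stomach, and 34 elevated in lung. With it aorta gave 364 and 683 against brain, 418 higher against heart, 297 and 375 against kidney, 444 higher against liver, 125 and 183 against lung, 347 and 321 against spleen and 253 and 277 against stomach. TPM gave 607 lower in aorta, 43 elevated in aorta and 36 in spleen, and FLI1 in spleen at 2.34 (permutation adjusted p = 0.0553). Median-ratio scaling gave 426 higher and 400 lower in heart and FLI1 in spleen at 2.31 (permutation adjusted p = 0.0929). Quantile normalization gave 851 lower in brain, 426 and 358 in heart, 441 and 452 for aorta against heart, 240 lower for aorta against lung, SENCR in spleen at 0.00153 and FLI1 in brain at -2.50 (permutation adjusted p = 0.0455). Without mitochondrially encoded genes FLI1 in spleen was 2.33 (permutation adjusted p = 0.0553). Over all settings other than single libraries left out, the replicate block included, the adjusted p of FLI1 ran from 0.0158 to 0.0929 in spleen and from 0.0290 to 0.0929 in brain. With no minimum difference, which admits smaller changes, there were 659 and 894 in aorta, 822 lower in brain, 1550 lower in heart, 720 and 733 in kidney, 704 and 1365 in liver, 859 and 496 in lung, 845 and 1076 in spleen, 588 and 588 in stomach, and 126 elevated in liver and 128 in spleen. With voom on recovered reads 597 were lower in aorta, 989 in brain, 448 in lung and 1089 in spleen, and FLI1 in brain was -2.31 (permutation adjusted p = 0.0494). Without aorta replicates 1 and 3 there were 41 elevated in aorta, 233 lower against lung and 287 higher against stomach, and the mitochondrial list's mean was -0.0159. With an estimated correlation 11 list tests were called. By label, libraries of different tissues were linked only through a replicate number. Over 84 same-number pairs the median r was 0.0241 (2 over 0.1), against -0.0173 over 168 others. Yet 20 of 24 libraries correlated best with their own number. Libraries of different tissues may therefore not be independent, which the main tests assume. With the replicate block FLI1 passed in brain (-2.23) and lung (2.14, permutation adjusted p = 0.0290 for both), and no count moved by over 1.5 times. Low depth limits SENCR, with 11 reads in the 3 liver libraries.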

Other observations

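All tests of explanations given here were chosen after the results were seen. Of 15 skeletal muscle genes in the table, the 7 that passed the filter were all higher in lung. This was so under each of the deposited, TPM, median-ratio and quantile scalings. A gene that passed the filter through lung alone would be higher there by construction. Lung held MYOZ1 at 69.6 ± 45.9 FPKM, MYH2 at 22.1 ± 9.87 and ACTA1 at 22.3 ± 25.3 (SD, n = 3), and the list's call was lost with an estimated correlation (adjusted p = 0.166). In lung 4 of 13 cardiomyocyte genes and 4 of 9 smooth muscle genes were also higher and none lower, and these lists were not called (camera adjusted p = 0.674 and 0.104).

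FLI1 was lowest in replicate 2 of each of the 8 tissues, by a mean of -1.11 ± 0.39 (SD over 8 tissues) on the log2(FPKM + 1) scale (permutation p = 1e-05, the smallest the permutations can give), at 0.290 to 0.642 times the mean of the other 2 libraries. It ranked 1 of 4260 genes for an effect of replicate number (limma adjusted p = 0.000269), and 5 genes were called. Median-ratio scaling left the difference in place (-1.10), against scaling between libraries as the cause. Thinning to equal depth gave -1.14, but it keeps the expected level of a gene and so cannot decide on depth. Endothelial and blood cell genes moved by a median of -0.055 over 12 pairs of gene and tissue (SE 0.18), 8 of them lower. The pairs ranged widely, with TEK in lung at -0.59 and SPI1 in liver at 1.12. No pair came from brain, kidney or stomach, and pairs from the same library are not independent. These pairs therefore cannot decide on fewer such cells. SENCR was lower in replicate 2 in 6 of 8 tissues but higher in heart and liver (permutation p = 0.0403, limma adjusted p = 0.447). The permutation test asks about any shift with replicate number, not a fall in replicate 2. Reads of SENCR and FLI1 could not be told apart with certainty. SENCR therefore cannot decide on lower output of the whole transgene in those libraries, which stays a hypothesis. ETS1 moved by -0.064 (permutation p = 0.453), and whether it lies on the transgene is not known. The labels do not tie numbers to animals, so a difference between animals was not tested.

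Mitochondrially encoded genes had 363 reads in aorta replicate 1 and 216 in replicate 3, shares of 0.0962% and 0.0577%, against 0.00154% in aorta replicate 2. The highest share in a heart library was 0.00340%, which argues against mouse mitochondrial RNA, since heart is rich in mitochondria. ALB had 37 reads in the same 2 aorta libraries and 1 in the 3 liver libraries, so traces of human RNA or DNA may be present, as a hypothesis. ALB reads were not confined to aorta: replicate 3 of each tissue had some (26 in aorta, 8 in spleen, 4 in heart and stomach, 2 in brain, 1 in kidney, liver and lung), as did replicate 1 of aorta (11), heart (2) and kidney (1), and replicate 2 had none in any tissue. Aorta replicates 1, 2 and 3 had 469, 44 and 109 genes seen in no other library, and no biological explanation was tested.

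Genes of one complex or cell type had very uneven levels. Of 28 ribosomal protein genes, 13 had no reads in the 3 spleen libraries while RPLP0 had 9808 of 1401405, which argues against low depth, and 12 of 16 hepatocyte genes were under 1 FPKM in liver. The order of ribosomal protein genes was alike between tissues (median Spearman rho 0.860 over 28 tissue pairs, 0.743 to 0.978, across genes, which are not independent replicates). A fixed share of mouse reads kept per gene on the human build may explain this, as a hypothesis. No biological explanation was tested.

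Other splits of the libraries were counted for each comparison. Splits other than the real one mixed tissues within groups, which widened the spread. Fewer calls were therefore built in, so these splits cannot show how many calls are chance. In each tissue against the others, 1 of 100 splits, the real one, called as many genes. It called 757 in aorta against at most 345 in another split, 1468 against 412 in brain and 1016 against 463 in heart. Kidney had 762 against 498, liver 1155 against 422, lung 663 against 436, spleen 1064 against 407 and stomach 576 against 454. The 1027 tissue-elevated genes stood against at most 33. For aorta against a single tissue, 10 splits are too few for a share under 0.05, and 1 of 10, the real one, called as many: 1583 against at most 4 for brain, 966 against 7 for heart, 1091 against 4 for kidney, 1324 against 2 for liver, 560 against 8 for lung, 1087 against 2 for spleen and 907 against 6 for stomach.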
